A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

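RNA was measured in 6 libraries from aerobic, glucose-limited chemostat cultures of Saccharomyces cerevisiae, 3 of the mutant strain IMY104 and 3 of the reference strain CEN.PK113-7D. Per the labels, each library comes from an independent culture. Per the labels' protocols, total RNA was turned into cDNA, fragmented by nebulization and made into libraries with a DNA library kit, with inserts of about 350 bp, and sequenced as read pairs on an Illumina instrument. The protocols name no step that marks the strand, so reads of a gene and of an overlapping antisense partner cannot be told apart.

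The authors' processed data are one table that compares the strains. Per the submitters' processing notes, the tools were CASAVA 1.8.2, BWA 0.5.9-r16, SAMtools 0.1.7-r510, Cufflinks and Cuffdiff, listed without roles. The versions of the last pair, the genome build and the scaling between libraries are not given in the sources used here. Per the file headers, the authors combined the 3 libraries of each strain into one FPKM value, fragments scaled to the length of the gene model and to the total of fragments. The authors' deposited table also holds the log2 fold change of IMY104 over CEN.PK113-7D, a signed fold change, a test statistic (a score that is positive where IMY104 is higher), a p-value, a q-value and a call. Its columns are those of a Cuffdiff comparison. Gene models are predictions by the program JIGSAW on an assembly of the CEN.PK lineage with the plasmid pUDC140 added, per the file's model names. The coordinates printed here are those of that assembly, counted from 1, and were not converted to another build.

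The table held 5479 gene models, of which 7 lie on the plasmid, and 5447 blank lines, which were dropped. The authors tested all but 16 models, and most of the untested ones are fragments of the mitochondrial genome. The deposited log2 fold changes equalled the log2 ratio of the FPKM values within a tolerance of 0.0001. The deposited q-values equalled Benjamini-Hochberg values recomputed from the deposited p-values within a tolerance of 1e-06. The smallest p was 5e-05, shared by 581 models, so the strongest changes cannot be ranked by p and carry the same q of 0.00047. Every called model had a q-value under 0.05, the largest being 0.0495. Spreadsheet error values in the fold change columns were read as a level of 0 in IMY104.

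Gene symbols came from the annotation of assembly R64, used for names and for the order of neighbours only. Of 5361 distinct systematic names, 5357 matched it. A further 34 models had no name. Some 72 names stood on more than 1 model, 149 models in all, so a gene could be split into pieces. In 46 models the name belonged to a gene of another chromosome, and these were kept out of the gene lists. Several near-identical copies had no model under their own name and are not analysed here, among them PDC5, ALD2, HXT6, HXT7, SSA1, SSA2, ENO2 and ADH1. Reads of such copies can add to the model of a paralog, so values of PDC1, ENO1 and members of the hexose transporter family are less certain. The models hold coding sequence, and lengths given here run from the first to the last base of a model, any intron included.

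A test across libraries had been designed before the data were examined: limma on log2 FPKM of all 6 libraries, with the authors' values used as such if only their comparison was given. The second case applied. The table gives no value per library, so no SD, no leave-one-out value, no other split of the libraries and no depth per library could be had, and the precision behind each value is known only through the authors' test. The number of whole reads could not be recovered, because the values are combined over libraries. Calls are therefore the authors' own, at q under 0.05, and a second count required a change of at least 2-fold as well.

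In place of the planned camera test on libraries, 45 gene lists with at least 3 tested members were tested with the cameraPR function of limma 3.58.1 in R 4.3.3. It was run on ranks of the authors' test statistic with a preset correlation of 0.01 between genes of a list, and Benjamini-Hochberg adjustment over the 45 lists. This tests a list against the other genes of the same comparison, and the spread between cultures enters only through the authors' statistic. One model per gene, the longest, entered, and ACS1, ACS2 and the plasmid genes were left out, which gave 5408 genes. An estimated correlation needs values per library, so a preset correlation of 0.05 was used as the stricter setting. For each list the median log2 fold change was also placed among the medians of 10000 random lists matched on mean FPKM in 20 bins. Members of a list were counted as higher or lower by the authors' q-values over all models and, separately, by Benjamini-Hochberg values adjusted over the list alone. Of 47 lists fixed in advance, the plasmid genes and the mitochondrially encoded genes, with 1 tested gene, were not tested as lists.

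The list test was tested on simulated data made by shuffling the statistics over 5408 genes and turning their ranks into normal scores. Shifts are in SD of these scores. All simulated lists held 20 genes, so the rates do not cover smaller or larger lists. The shuffle leaves no correlation between members of a list, so these rates hold for independent genes only. It recovered 92.5% of 200 lists of 20 genes shifted by 1 SD and 100% of those shifted by 2 or 3 SD. It called 0.25%, 0.5% and 0.25% of 800 unchanged lists in error at these 3 shifts.

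Genes named in the text follow a rule set before the data were examined. It took the deleted genes, the plasmid genes, and the 12 largest rises and 12 largest falls among called models with at least 10 FPKM in the higher strain. It also took up to 4 called members with the largest change per described list, the members of the pyruvate bypass list and the subunits of mitochondrial pyruvate dehydrogenase. The rule's condition on overlap between libraries could not be applied. Lists described in full were those past the list test and those about acetyl-CoA, 26 in all. Genes named outside the rule are said to be chosen after their values were seen. GCD6, EXG2, YDR262W and DIN7, which mark a stretch of chromosome 4 described below, were chosen in that way too.

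Alternatives planned before the data were examined were other pseudocounts (0.1 and 5), a minimum mean of 10 FPKM, rescaling to the same median, quantile normalization and a q threshold of 0.01. Alternatives added after seeing the data were a pseudocount of 1, a minimum of 1 FPKM, a normal distribution for the statistic, 1 model per gene, models of at least 300 bp, other forms of the list test, and leaving out a run of neighbouring genes on chromosome 4. That run was found by ordering 5399 genes along the 16 chromosomes and taking the longest stretch on one side of the median, compared with 1000 shuffles of the gene order. Intervals of medians and ratios are 95% bootstrap intervals from 2000 draws over genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.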

Results

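RNA was measured in chemostat cultures of 2 strains of Saccharomyces cerevisiae, with 3 libraries per strain from independent cultures. CEN.PK113-7D, a prototrophic laboratory strain, was the reference. IMY104 lacks ACS1 and ACS2, which encode the acetyl-CoA synthetases that make cytosolic acetyl-CoA from acetate. It carries a plasmid with genes of the bacterium Enterococcus faecalis for a pyruvate dehydrogenase complex and for attaching lipoic acid to it. Both strains grew aerobically under glucose limitation at a dilution rate of 0.10 per h, 30 °C and pH 5.0, on medium with 7.5 g/L glucose and 500 ng/mL lipoic acid. The authors' deposited table gives 1 FPKM value per strain and the authors' test, with no value per library, so no SD or depth is given here and the depth is unknown.

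The comparison asked how gene expression differs between a strain that draws cytosolic acetyl-CoA from a bacterial pyruvate dehydrogenase and the reference strain. In IMY104 the general stress, heat shock and peroxisomal fatty acid oxidation genes were lower as groups, and the genes of the respiratory chain and the mitochondrial ribosome were higher. Most tested genes of the native route from pyruvate to acetate fell, with ALD4, the mitochondrial acetaldehyde dehydrogenase, 1.89-fold lower in the authors' deposited table. CIT2, the peroxisomal citrate synthase, was 4.03-fold higher and the cell wall mannoprotein gene FIT2, which helps retain iron siderophores, was 3.02-fold higher in the authors' deposited table.

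Of 5479 gene models, all but 16 of them tested, the authors' deposited table called 1235 (22.6% of those tested), 634 higher and 601 lower in IMY104. Most changes were small. The median absolute log2 fold change of the called models was 0.39, and 103 of them changed at least 2-fold, 45 up and 58 down, in the authors' deposited table (38 and 56 without the plasmid and ACS genes). With a pseudocount of 5 FPKM the 2-fold changes were 28 up and 56 down. Over the chromosomal genes tested, the median log2 fold change was 0.0082, with quartiles of -0.11 and 0.14, so the strains were centred on one another. The median FPKM was 83.3 in CEN.PK113-7D and 84.9 in IMY104 in the authors' deposited table.

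The deleted genes and the plasmid genes matched the labels. The level of ACS1 (YAL054C, chromosome 1, 42935 to 45076) was 1094 FPKM in CEN.PK113-7D and 0.882 in IMY104 in the authors' deposited table. ACS2 (YLR153C, chromosome 12, 430526 to 432577) had 494 and 0.179 FPKM in the authors' deposited table. The pyruvate dehydrogenase subunits carried by the plasmid had levels in IMY104 of 10685 FPKM for E3 and 9655 for E1 beta against 4191 for E1 alpha and 1748 for E2 in the authors' deposited table. The lipoylation genes LplA2 and LipA1 had 2754 and 1226 FPKM and the plasmid's ampR gene 344 in the authors' deposited table. In CEN.PK113-7D, which has no plasmid, these 7 genes were listed at 0.0216% to 0.0634% of their level in IMY104. The deleted genes were listed in IMY104 at 0.0806% (ACS1) and 0.0362% (ACS2) of their reference level.

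**Figure D1:**
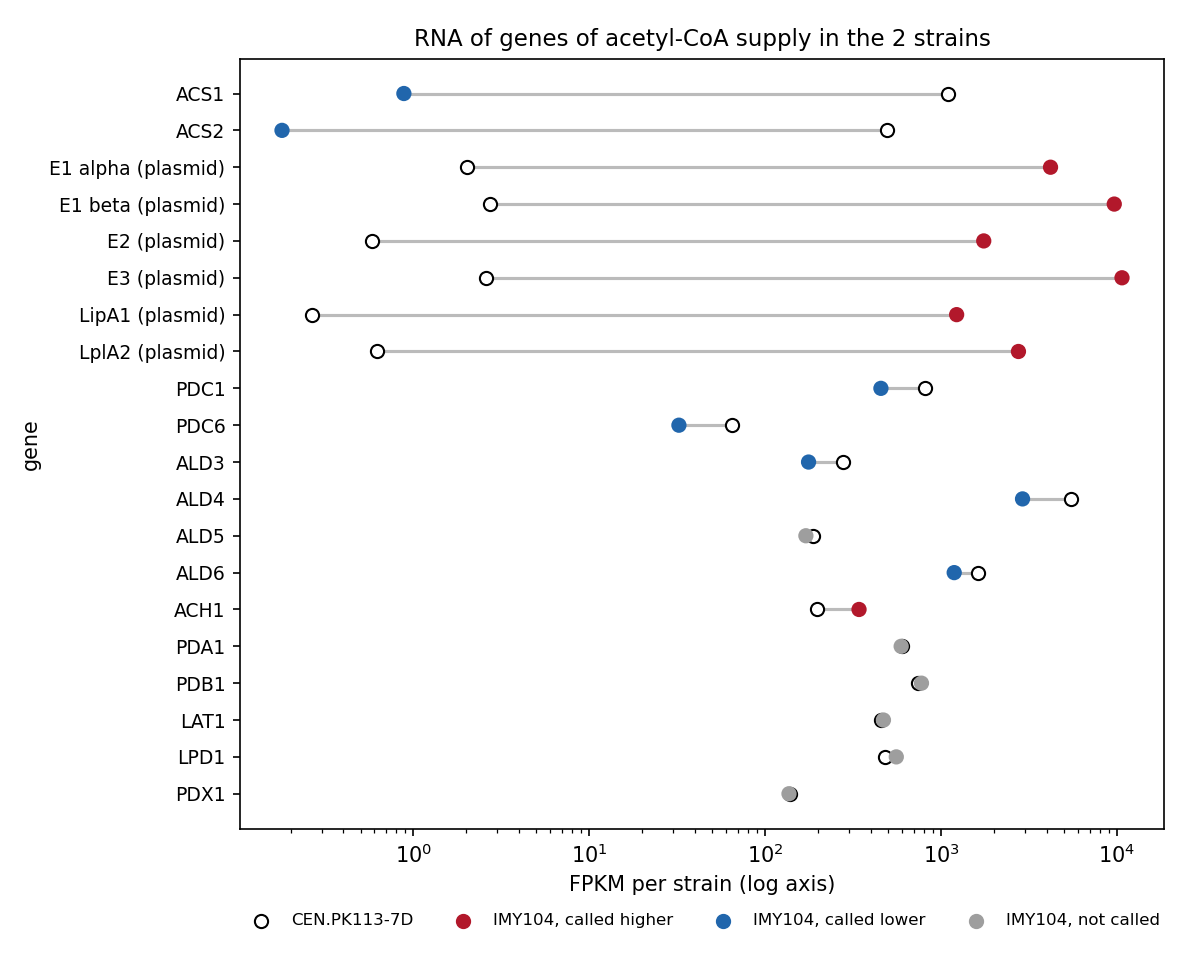
FPKM on a log axis (horizontal) of genes of acetyl-CoA supply (vertical), with open circles for CEN.PK113-7D and filled circles for IMY104, coloured by the authors' call; each circle is 1 value per strain in the authors' deposited table. ACS1 and ACS2 were near 0 in IMY104, the bacterial genes were near 0 in CEN.PK113-7D, and the mitochondrial pyruvate dehydrogenase genes PDA1, PDB1, LAT1, LPD1 and PDX1 lay close together in both strains.

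The pyruvate bypass, which turns pyruvate into acetaldehyde and acetate ahead of the deleted enzymes, was lower. Of its 7 tested members 5 fell, 1 rose and 1 was not called, and 6 were called when adjusted over the list alone. The list had a median log2 fold change of -0.65 (cameraPR, adjusted p = 0.0166). The pyruvate decarboxylases PDC6 and PDC1 fell, with log2 fold changes of -0.99 and -0.83, and the aldehyde dehydrogenases ALD4, ALD3 and ALD6 fell, with -0.92, -0.65 and -0.45, in the authors' deposited table. ALD5 had -0.13 and was not called in the authors' deposited table. The exception was ACH1, a mitochondrial enzyme that moves coenzyme A between acetate and other acids, which rose with a log2 fold change of 0.80 in the authors' deposited table. ALD3 rests on a model of 180 bp and counts in the general stress list too. With models of at least 300 bp only, the list was close to the threshold (cameraPR, adjusted p = 0.0494). PDC5 and ALD2 had no model of their own.

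The yeast's own mitochondrial pyruvate dehydrogenase showed no called change. The log2 fold changes were -0.02 for PDA1, 0.06 for PDB1, 0.05 for LAT1, 0.21 for LPD1 and -0.01 for PDX1, none of them called in the authors' deposited table. Among the 16 genes of the complex, its regulators, lipoylation and pyruvate import, 3 rose and 2 fell (5 adjusted over the list alone), and the list did not pass its test (cameraPR, adjusted p = 0.979). The genes called were mostly those of the mitochondrial pyruvate carrier: MPC1 and MPC3 fell, with log2 fold changes of -0.73 and -0.70, and MPC2 rose with 0.62 in the authors' deposited table. The lipoic acid synthase gene LIP5 rose with 0.32 in the authors' deposited table.

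In fatty acid synthesis 4 of 10 genes fell and none rose (5 called when adjusted over the list alone, 1 of them higher), and the list did not pass its test (cameraPR, adjusted p = 0.149). ACC1, the acetyl-CoA carboxylase, had a log2 fold change of -0.53, the fatty acid synthase subunit FAS1 -0.52, the acyl-CoA binding protein ACB1 -0.37 and the desaturase OLE1 -0.32 in the authors' deposited table. In ergosterol synthesis 7 of 23 genes rose and 1 fell (9 adjusted over the list alone), with a median log2 fold change of 0.15 (cameraPR, adjusted p = 0.0433, and adjusted p = 0.149 with a preset correlation of 0.05). ERG12, the mevalonate kinase, rose with 0.46, ERG7 with 0.45, ERG26 with 0.44 and ERG4 with 0.40 in the authors' deposited table. Of 4 carnitine shuttle genes, which carry acetyl units between compartments, the carrier CRC1 and the acetyltransferase YAT2 rose, with log2 fold changes of 1.04 and 0.81 in the authors' deposited table (2 adjusted over the list alone; cameraPR, adjusted p = 0.0815). Among random lists matched on expression, the medians lay at the percentile 17.4 for fatty acid synthesis, 99.9 for ergosterol synthesis and 99.9 for the carnitine shuttle.

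The glyoxylate cycle, gluconeogenesis and acid transport list split, with 4 of 16 genes higher and 7 lower (11 adjusted over the list alone; cameraPR, adjusted p = 0.104). CIT2 (YCR005C, chromosome 3, from 120613) rose from 417 to 1682 FPKM, and the malate synthase MLS1 rose with a log2 fold change of 1.19 in the authors' deposited table. The lactate and pyruvate permease JEN1 fell with -1.24 and the acetate transporter ADY2 with -1.10 in the authors' deposited table. Of 16 tricarboxylic acid cycle genes, IDH2 rose with 0.39 and LSC2 fell with -0.39 in the authors' deposited table (2 adjusted over the list alone; cameraPR, adjusted p = 0.418). Of 32 genes for histone acetylation and deacetylation, HDA1 rose with 0.25 and SIR4 fell with -0.53 in the authors' deposited table (1 adjusted over the list alone; cameraPR, adjusted p = 0.335). Among matched random lists, the medians lay at the percentile 0.41 for the glyoxylate list, 95.8 for the tricarboxylic acid cycle and 15.2 for histone acetylation.

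Stress genes were the group with the lowest median. Of 23 general stress response genes 18 fell, 1 rose and 4 were not called (20 adjusted over the list alone), with a median log2 fold change of -0.71 (cameraPR, adjusted p = 1.35e-08). GRE1, a hydrophilin gene induced by stress, fell with -2.20, the carbonic anhydrase NCE103 with -2.13, the secreted glycoprotein gene YGP1 with -1.89 and the membrane heat shock gene HSP30 with -1.76 in the authors' deposited table. Of 20 heat shock and chaperone genes 15 fell and none rose (17 adjusted over the list alone; cameraPR, adjusted p = 3.01e-07). BTN2 fell with -1.55, the HSP70 genes SSA4 and SSA3 with -1.36 and -1.26, and SSE2 with -1.22 in the authors' deposited table. Of 24 oxidative stress genes 11 fell and 1 rose (14 adjusted over the list alone; cameraPR, adjusted p = 0.00124). The peroxidases GPX1 and AHP1 fell with -1.18 and -1.06 and OYE3 with -0.98, and the sulfiredoxin SRX1 rose with 0.78 in the authors' deposited table.

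Peroxisomal fatty acid oxidation fell as a group, with 12 of 16 genes lower and none higher (14 adjusted over the list alone) and a median log2 fold change of -0.46 (cameraPR, adjusted p = 4.8e-07). The peroxisomal catalase CTA1 fell with -1.46, the enoyl-CoA isomerase ECI1 with -0.87, IDP3 with -0.79 and the fatty acid importer PXA1 with -0.75 in the authors' deposited table. Trehalose and glycogen metabolism had 7 of 19 genes lower and none higher (8 adjusted over the list alone; cameraPR, adjusted p = 0.00391). GAC1, TPS2, PGM2 and GLG1 fell with log2 fold changes of -0.57, -0.57, -0.51 and -0.49 in the authors' deposited table. Proteasome genes were shifted down together by a small amount, with a median log2 fold change of -0.19 and 3 of 33 called lower (3 adjusted over the list alone; cameraPR, adjusted p = 5.76e-07). Those 3 were RPN4, the transcription factor of the list, with -0.63, PRE10 with -0.29 and RPN12 with -0.27 in the authors' deposited table.

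Genes of the respiratory chain and of the mitochondrial ribosome were shifted up. In the respiratory chain and ATP synthase 13 of 33 genes rose and 1 fell (15 adjusted over the list alone), with a median log2 fold change of 0.19 (cameraPR, adjusted p = 4.17e-08). Cytochrome c (CYC1) rose with 0.53, QCR2 with 0.44, COX12 with 0.38 and QCR6 with 0.35 in the authors' deposited table. Of 67 mitochondrial ribosomal protein genes 13 rose and 1 fell (17 adjusted over the list alone), with a median of 0.17 (cameraPR, adjusted p = 3.79e-10), and RSM7 rose with 0.45, MRPL4 with 0.43, MRPL35 with 0.31 and RSM28 with 0.31 in the authors' deposited table. Ribosome biogenesis had 5 of 54 genes higher and none lower (4 adjusted over the list alone; cameraPR, adjusted p = 0.000425), among them NOP58 with 0.33, NOP16 with 0.33, MAK16 with 0.28 and NOP53 with 0.27 in the authors' deposited table. Cytosolic ribosomal proteins had a median log2 fold change of -0.068, with 3 of 106 genes lower and none higher (2 adjusted over the list alone; cameraPR, adjusted p = 6.25e-05). The list's median lay at the percentile 20.6 of random lists matched on expression, so it was not extreme for genes of that level. RPS22B, RPL22B and RPL8A fell with -0.41, -0.31 and -0.26 in the authors' deposited table. Of 9 histone genes 4 fell, HTB1 with -0.64, HTA1 with -0.51, HTB2 with -0.32 and HTA2 with -0.29 in the authors' deposited table (4 adjusted over the list alone; cameraPR, adjusted p = 0.00523; median at the percentile 4.49 of matched random lists).

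**Figure D2:**
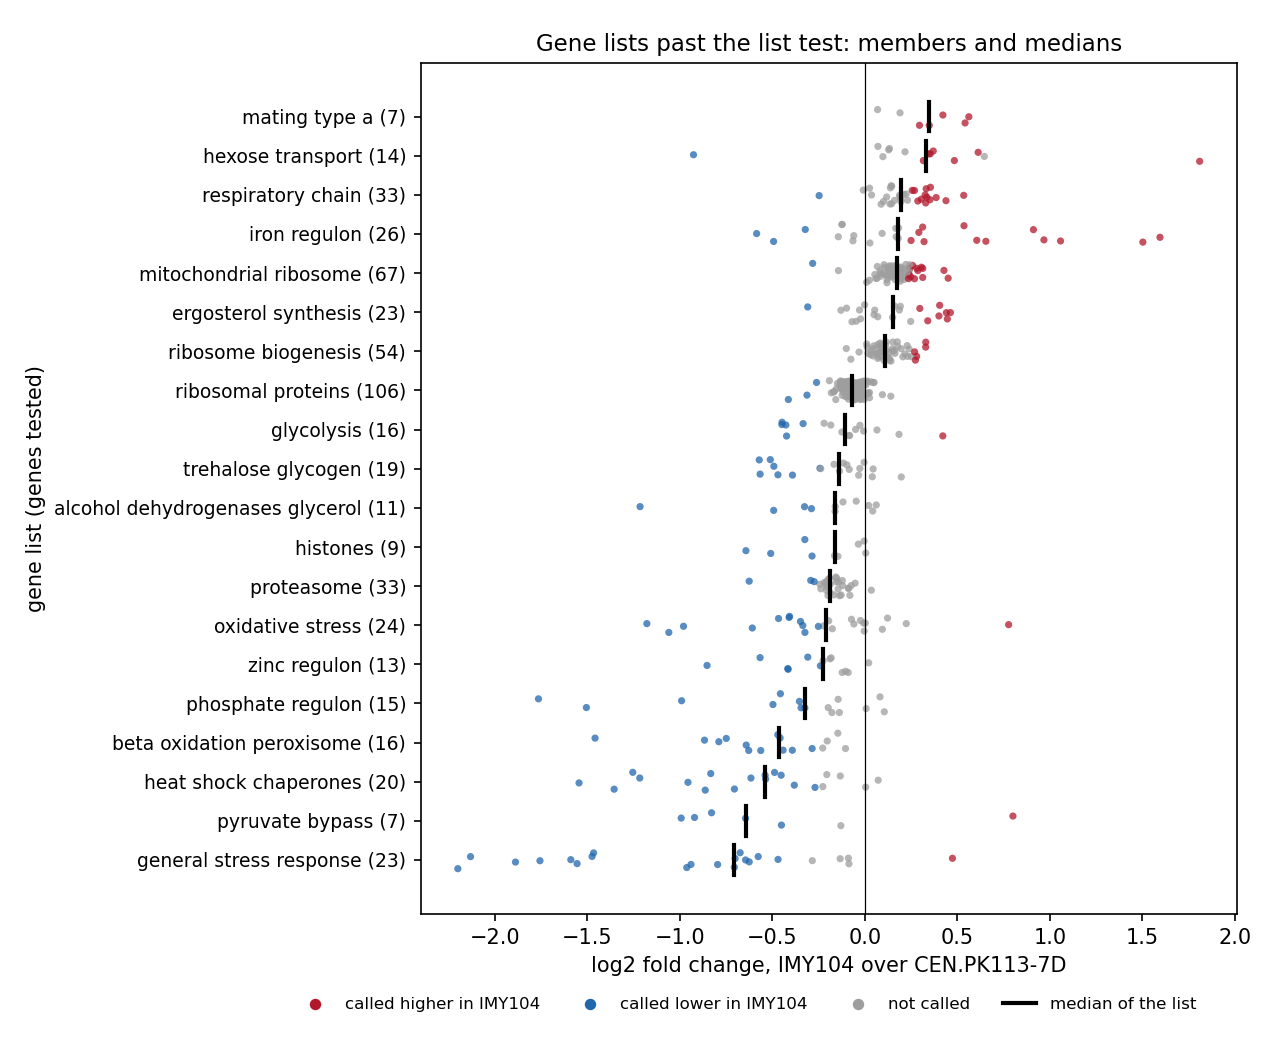
Log2 fold change of IMY104 over CEN.PK113-7D (horizontal) of the members of the 20 gene lists past the list test (vertical, number of genes tested in parentheses); each point is a gene in the authors' deposited table coloured by its call, spread vertically for display, and black bars are list medians. The medians run from 0.35 for the genes of mating type a to -0.71 for the general stress response.

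Nutrient genes moved in both directions. In the iron regulon 12 of 26 genes rose and 3 fell (15 adjusted over the list alone; cameraPR, adjusted p = 0.0143, and adjusted p = 0.088 with a preset correlation of 0.05). FIT3 rose 2.83-fold and FIT2 with a log2 fold change of 1.59, the siderophore transporter SIT1 with 1.06 and the iron oxidase FET3 with 0.97 in the authors' deposited table. In the zinc regulon 6 of 13 genes fell and none rose (7 adjusted over the list alone; cameraPR, adjusted p = 0.000374), with ZRT1, the high-affinity zinc transporter, at -0.85, IZH2 at -0.57, IZH1 at -0.42 and ZPS1 at -0.41 in the authors' deposited table. In the phosphate regulon 8 of 15 genes fell and none rose (8 adjusted over the list alone; cameraPR, adjusted p = 0.000512), with SPL2 at -1.76, the phosphate transporter PHO84 at -1.51, PHO3 at -0.99 and PHO89 at -0.50 in the authors' deposited table. PHO3 is also a member of the thiamine list and counts there as lower too. Of 14 hexose transport genes 7 rose and 1 fell (8 adjusted over the list alone; cameraPR, adjusted p = 0.00269). HXT4 rose with 1.81, HXT10 with 0.61 and HXT14 with 0.48, and HXT5 fell with -0.93 in the authors' deposited table. HXT14 had no more than 2.52 FPKM in either strain in the authors' deposited table, and its direction flipped under quantile normalization (-0.31).

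Glycolysis had 5 of 16 genes lower and 1 higher (6 adjusted over the list alone; cameraPR, adjusted p = 0.046, and adjusted p = 0.131 with a preset correlation of 0.05). Its median lay at the percentile 9.81 of random lists matched on expression, which is not extreme. GPM1 and TDH3 fell with -0.45 each, PGK1 with -0.43 and ENO1 with -0.42 in the authors' deposited table. Of 11 alcohol dehydrogenase and glycerol genes 4 fell and none rose (4 adjusted over the list alone; cameraPR, adjusted p = 0.0271, and adjusted p = 0.0747 with a preset correlation of 0.05). The glycerol importer STL1 fell with -1.22, GPP2 with -0.49, SFA1 with -0.33 and ADH6 with -0.29 in the authors' deposited table.

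Beyond the plasmid genes, the largest rises were in URA3, PBI1, CIT2, BSC1 and PRM7. URA3 (YEL021W, chromosome 5, from 114256), an enzyme of uracil synthesis and a common selection marker, rose from 142 to 1060 FPKM in the authors' deposited table. PBI1 rose from 42.9 to 268 FPKM, and the neighbours BSC1 and PRM7 rose with log2 fold changes of 1.96 and 1.94 from levels of 10.2 and 12.3 FPKM in the authors' deposited table. Beyond the deleted genes, the largest fall was in FAT3 (YKL187C, chromosome 11, from 89266), needed for fatty acid uptake, from 271 to 30.8 FPKM in the authors' deposited table. It was followed by YRO2 with -2.61, GRE1, NCE103, CRF1 with -2.07, the plasma membrane proton pump PMA2 with -1.95 and the transaldolase NQM1 with -1.94 in the authors' deposited table. YGP1, YER121W with -1.82, SPL2, HSP30 and NCA3 with -1.66 completed the 12 falls in the authors' deposited table.

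Genes specific to mating type a were expressed in both strains and 5 of 7 were higher in IMY104 (5 adjusted over the list alone; cameraPR, adjusted p = 0.00079). The pheromone genes MFA1 and MFA2, on models of 111 and 117 bp, rose with 0.56 and 0.54, the transporter STE6 with 0.42 and the receptor STE2 with 0.35 in the authors' deposited table. None of the 4 genes of mating type alpha was called (cameraPR, adjusted p = 0.312; 0 adjusted over the list alone). Of 7 marker genes 2 rose and 1 fell (4 adjusted over the list alone; cameraPR, adjusted p = 0.349). LEU2, chosen after its values were seen, was split into 3 models that all fell, with log2 fold changes of -1.27, -1.30 and -1.44 in the authors' deposited table. The table's name for the IMY104 libraries holds the name of another strain of the CEN.PK family, and the marker alleles of IMY104 are not given in the sources used here. The values of URA3 and LEU2 therefore cannot be assigned to the acetyl-CoA route.

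The remaining lists did not pass the list test, which does not show that they were unshifted. The leucine list's median of 0.25 lay at the percentile 100 of random lists matched on expression, and its 1 lower gene was LEU2. Medians of the meiosis and COS lists lay at 99.8 and 99.6, and that of the thiamine list at 0.97. Counts of genes higher and lower were 7 and 1 of 13 for leucine synthesis (adjusted p = 0.0815), 5 and 2 of 16 for meiosis (0.109), 4 and 2 of 15 for pheromone response (0.141), 1 and 2 of 15 for thiamine (0.145) and 7 and 3 of 24 for sulfur assimilation (0.2). They were 4 and 1 of 13 for hypoxic genes (0.302), 4 and 1 of 15 for maltose and galactose use (0.312), 5 and 2 of 12 for drug efflux (0.323), 2 and 1 of 20 for phospholipid synthesis (0.349) and 1 and 2 of 9 for lysine synthesis (0.349). They were 6 and 8 of 24 for nitrogen catabolite repressed genes (0.537), 6 and 3 of 21 for the cell wall (0.537), 2 and 5 of 14 for the pentose phosphate pathway (0.611) and 2 and 1 of 4 for the COS family (0.637). They were 3 and 3 of 12 for arginine synthesis (0.917), 1 and 2 of 9 for the PAU, DAN and TIR families (0.917) and 1 and 2 of 13 for biotin and coenzyme A (0.987). In the pentose phosphate and biotin lists the median log2 fold change was above 0 (0.014 and 0.012), while the mean (-0.28 and -0.019) and the test pointed down. Adjusted over the list alone, these lists held 9, 10, 7, 3, 10, 5, 6, 7, 3, 3, 16, 10, 7, 3, 8, 3 and 3 called genes in the order given. The mitochondrially encoded list had 1 tested gene, which was not called.

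Part of the lower genes lay side by side. On chromosome 4, between 883756 and 994562 of the authors' assembly, 48 neighbouring genes from GCD6 to DIN7 had log2 fold changes below the median of all genes, and 44 of them were called lower in the authors' deposited table. Their median log2 fold change was -0.51 (95% bootstrap interval -0.54 to -0.44 over genes), with quartiles of -0.59 and -0.40. The 20 genes before and the 20 genes after had medians of 0.03 each. The next longest run in the genome held 13 genes, and no chromosome had a median outside -0.0092 to 0.036. CRF1, CTA1, SIR4, HTA1 and HTB1 lie within this run, as do the chaperone genes AHA1 and HSP78 (both chosen after their values were seen), which counted among the heat shock genes. Outside the run the authors' deposited table called 1191 models, 634 higher and 557 lower, and 1182 (629 and 553) passed when the q-values were also recomputed over the models left. Without the run the histone list had an adjusted p of 0.0403 (cameraPR).

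**Figure D3:**
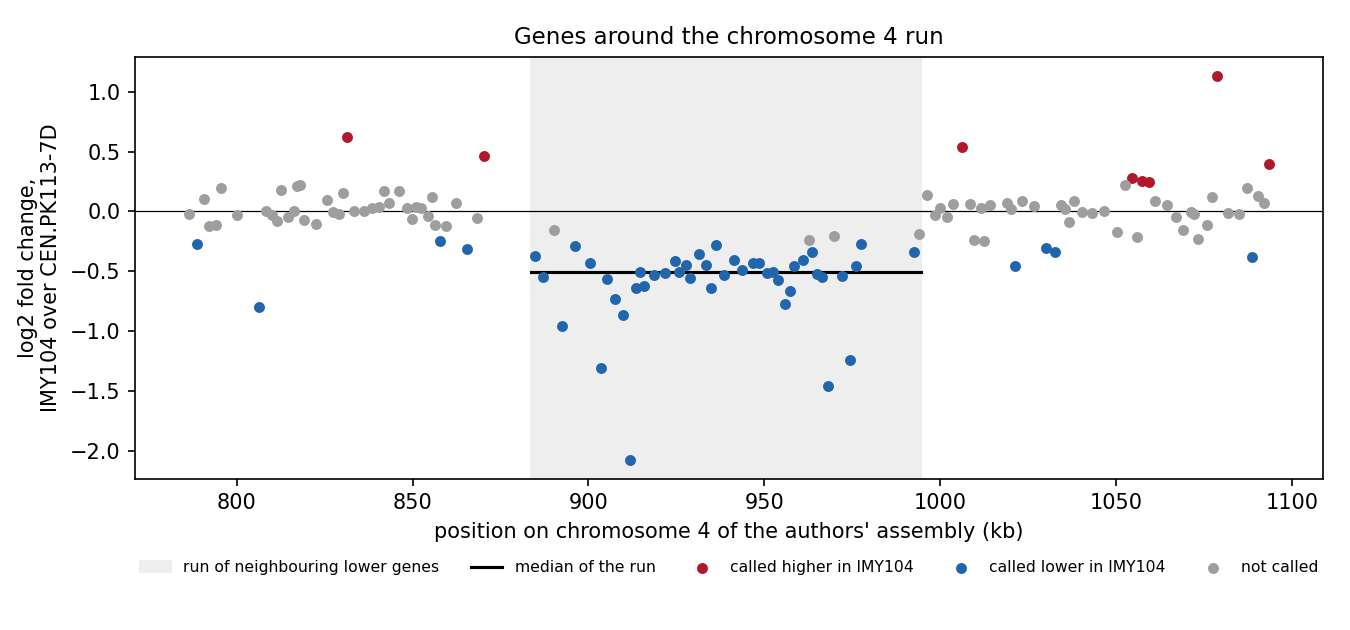
Log2 fold change of IMY104 over CEN.PK113-7D (vertical) against position on chromosome 4 in kb (horizontal); each point is a gene in the authors' deposited table coloured by its call, the shaded span is the run of 48 genes and the black line its median of -0.51. Genes on both sides of the span scatter around 0.

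The authors' calls rest on 3 cultures per strain that cannot be examined singly here. They fell to 814 when the statistic was read against a normal distribution, which the deposited p-values do not follow. Under that reading LIP5, OLE1, LSC2, SFA1, ADH6, HXT14, RPL8A, NOP58, NOP16 and MAK16 were not called. Nor were NOP53, MRPL35, RSM28, HDA1, STE2, PRE10, RPN12, GCD6 and EXG2. When the statistic itself replaced its ranks in the list test, the calls of the ergosterol, glycolysis, alcohol dehydrogenase, hexose transport, ribosome biogenesis, trehalose, zinc, histone and proteasome lists ended (adjusted p from 0.2 to 0.616).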

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

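The normal distribution, the forms of the list test other than rescaling, the length minimum, 1 model per gene, the minimum of 1 FPKM, the pseudocount of 1 and the removal of the chromosome 4 run were chosen after seeing the data. The count of 1235 called models fell to 814 (392 higher, 422 lower) when p was recomputed from the statistic under a normal distribution, and 730 models were called both ways. The deposited p-values do not follow that distribution: models under 300 bp had a median absolute statistic of 5.06, yet 31.6% of them were called. The fall in the count therefore does not by itself show which calls are unsound, and its cause was not tested. Other settings gave 877 models at q under 0.01. With q-values recomputed over the models kept, they gave 1194 at a mean of at least 10 FPKM, 1224 with 1 model per gene, 1176 for models of at least 300 bp and 1182 without the chromosome 4 run (1191 by the deposited q-values). The 103 models changed at least 2-fold ranged from 84 (28 higher, 56 lower) with a pseudocount of 5 to 105. The 20 lists past the test became 11 (4 higher, 7 lower) when the statistic replaced its ranks, and all 11 were among the 20; the cause was not tested. They became 16 at a preset correlation of 0.05, where the iron, alcohol dehydrogenase, ergosterol and glycolysis lists no longer passed. The same 20 passed with ranks of the log2 fold change, models of at least 300 bp, rescaling to the same median, and without the run. Among the 149 named models, changes of direction were counted for called models only. A pseudocount cannot change a direction, and rescaling to the same median moved log2 fold changes by only 0.0087. Under quantile normalization 1 called model changed direction, HXT14, at -0.31. Under the normal distribution 19 named models were no longer called. Alternatives that need a value per library could not be run: leaving out each library, limma with other settings, count models, fry and camera with an estimated correlation. No paired analysis was possible because the table gives 1 value per strain. Depth is unknown, so changes below the authors' threshold are not shown to be absent.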

Other observations

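The genes named in this paragraph, NQM1 and NCE103 apart, were chosen after their values were seen. The pentose phosphate, nitrogen, leucine and hypoxic lists did not pass the list test. In the pentose phosphate list the transketolase isoform TKL2 fell with NQM1, with log2 fold changes of -1.66 and -1.94, while the main isoforms TKL1 and TAL1 had 0.18 and -0.13 and were not called in the authors' deposited table. Among nitrogen-regulated genes the permeases GAP1, MEP2 and PUT4 fell with -0.75, -0.54 and -0.44, and the allantoin genes DAL1 and DAL4 rose with 0.52 and 0.47 in the authors' deposited table. These are examples from a mixed list of 24 genes, with 6 higher, 8 lower and 10 not called, and neither subgroup was tested. In leucine synthesis BAT1, LEU1 and OAC1 rose with 0.71, 0.65 and 0.49 in the authors' deposited table, against the fall of LEU2. The hypoxic isoforms COX5B and CYC7 rose with 0.77 and 0.65 in the authors' deposited table. Of the 13 genes of the hypoxic list 4 were higher, 8 were not called and 1, NCE103, was lower, with -2.13. The proton pump PMA1 fell with -0.52, and the short genes COX26 and COQ21, on models of 201 bp, rose with 0.93 and 0.98 in the authors' deposited table. Over the 7 plasmid genes, the low level listed in CEN.PK113-7D followed the level in IMY104 (Spearman's rho 0.964, 2-sided exact permutation p = 0.00278, across genes, which are not independent replicates).

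The tests of the chromosome 4 run, of the spread of short models and of scaling as a source of the stress pattern were chosen after the results were seen. The run of 48 neighbouring lower genes on chromosome 4 was not a matter of chance order, since the longest run in 1000 shuffled genomes held 23 genes. Only 10 of its genes were members of a fixed list, so list members alone did not make up the run. The 38 genes in no list had a median log2 fold change of -0.51. The run was picked for lying low and had an upper quartile of -0.40. Leaving out 10 genes could therefore hardly have moved its median, which decides nothing more about the lists. Doubling of the segment in all 3 reference cultures would put the median near -1, if RNA follows copy number, and the measured -0.51 (95% bootstrap interval -0.54 to -0.44) lies above that. The interval covers the spread over genes of the run, which were picked for lying low, and not the spread between cultures. The interquartile range in the run was 0.724 times that of all genes, but the run was picked for lying on one side of the median, and the other genes on that side gave 0.659, so the spread decides nothing; 91.7% of the run was called lower against 20.6% of those genes. More copies in part of the reference cultures or cells, or fewer in part of those of IMY104, cannot be told apart from other causes. DNA was not measured and no value per culture is used here. In assembly R64 the gaps next to GCD6 and between EXG2 and YDR262W each hold 4 retrotransposon genes. The second gap lies inside the run, since YDR262W (log2 fold change -0.34, called lower) and DIN7 (-0.19, not called) lie beyond it.

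The fall of general stress genes could reflect a technical offset, the statistics of short models or a growth-like shift. The median of all genes lay 0.714 above that of the list on the log2 scale, more than the interquartile range of all genes (0.25). An equal offset of all genes would leave that gap as it is, so it does not account for the gap. The list stood out for its low median, so the bound for an offset could hardly have been met. Without models under 300 bp the list kept a median of -0.71 over 21 of its 23 genes (cameraPR, adjusted p = 9.35e-08). So few members were short that leaving them out could hardly have ended the call, and the test decides little. The 21 genes left are not short, so their fall does not rest on short models, and the fold changes do not use the statistic. A shift as with faster growth needs ribosomal protein genes to rise, and their median was -0.068 with none of 106 called higher, although ribosome biogenesis genes had a median of 0.11. The ribosomal protein list ranked low (cameraPR, adjusted p = 6.25e-05) with a median at the percentile 20.6 of matched random lists, and the bound set before the test asked for both lists at 0 or below, so a growth-like shift cannot be told apart from none. By the labels both strains had a dilution rate of 0.10 per h, which sets the growth rate of a chemostat at steady state. That argues against faster growth of IMY104 itself, while the ribosome lists leave a growth-like pattern of RNA undecided. A difference due to the engineered acetyl-CoA route, to other strain differences or to other culture conditions stays open as untested.

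Models under 300 bp carried large statistics, with an absolute value over 20 in 21 of 174 short models against 3 of 4581 models of at least 600 bp, the deleted and plasmid genes left out. The spread implied by the authors' statistic, its log2 fold change divided by the statistic, was 0.288 times as large in short models as in long ones matched on FPKM (95% bootstrap interval 0.256 to 0.307). That ratio largely restates the size of the statistics, so by itself it does not show where they come from. Larger changes of short genes cannot be told apart from none, as the ratio of median absolute log2 fold changes was 1.26 (0.953 to 1.51). Median absolute statistics were 5.06 in short models and 1.01 in the matched long ones. That gap is wider than the upper bound of 1.51, so larger changes alone do not account for it. The share called was 31.6% in short models and 32.2% in the matched long ones.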
